A study of Zea mays with 54 samples.

How the data were processed

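The samples came from the vegetative shoot apical meristem (SAM) of the maize inbred line B73, taken from seedlings grown for 14 days. Cells of the L1, the outermost layer of the meristem and the source of the epidermis, and of the L2, here the corpus beneath it, were collected by laser microdissection of sections. Per the labels, RNA from 5 to 10 SAMs was pooled for each biological replicate, about 1 ng was amplified, and the amplified L1 and L2 RNA of a replicate was labelled with Cy3 and Cy5 and hybridised together on a spotted cDNA slide. There were 18 slides, 6 of each of 3 array designs, named here by slide number (slides 1 to 6, 7 to 12 and 13 to 18). On odd slides the L1 carried Cy3 and the L2 Cy5, and on even slides the dyes were exchanged. Every slide was read 3 times under the letters L, M and H, whose meaning is not given in the sources used here, which makes 54 columns. The labels number the RNA extracts. L1 numbers 1 to 5 and L2 numbers 2 to 4 recur on all 3 array designs, so the designs are not independent sets of plants. On slides 1 and 5 the labels give different numbers for the L1 and the L2 extract (1 with 2, and 5 with 6), so slides 1 and 2, and 5 and 6, share an L2 number.

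The deposited values are log ratios of the 2 channels of a slide, read as such from their signs, their range of -7.77 to 8.37 and column medians between -0.0773 and 0.0597. How the authors normalised them, the base of the logarithm and the dye in the numerator are not given in the sources used here. The design of the tests was written for base 2. The values do not separate base 2 from the natural logarithm, so differences are given in log units, and folds under both bases. Each probe had a value in every column of its array design or in none, and 4799, 5089 and 1730 probes of the 3 designs had none.

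The sign of each slide was read from the correlation between slides. Slides of like dye orientation correlated with a median r of 0.451 (slides 1 to 6), 0.269 (slides 7 to 12) and 0.271 (slides 13 to 18). Slides of opposite orientation had a median r of 0.0265, -0.164 and -0.162, with 3, 7 and 7 of 9 pairs below 0. The values were therefore treated as Cy5 over Cy3 and turned so that a positive value means more transcript in L1. On slides 1 to 6 the criterion fixed for this step, a negative correlation between opposite orientations, was not met. There the same reading was taken from the other two designs and from the genes shared with them, a choice made after seeing the data. That Cy5 is the numerator is likely but not stated. It was read from the lists "epidermis and cuticle" and "knox and corpus", whose medians were 0.71 and -0.19 on slides 1 to 6, 0.47 and -0.14 on slides 7 to 12, and 0.40 and 0.02 on slides 13 to 18. On the last design both medians were above 0, and its direction was taken from its likeness to the other two. The direction of these lists is therefore not independent evidence on the layers.

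The L, M and H values of a slide were averaged, since they read the same pair of extracts, and each slide counted as 1 replicate. Probes needed values on at least 4 slides, 2 of each orientation. For each array design on its own, limma (version 3.58.1, in R 4.3.3) fitted a layer term and a dye term per probe with lmFit and eBayes, leaving 4 residual degrees of freedom. Two-sided p-values were adjusted by Benjamini and Hochberg over all probes of the design with values, and a probe was called at an adjusted p under 0.05. The p-values measure the spread between the 6 slides of a design, which differ in their L1 extract numbers. They treat slides 1 and 2, and 5 and 6, as independent in spite of the L2 numbers they share. For arrays, their number limits the precision, and the number of slides per design was 6. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

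Gene names came from the annotation of the array designs, matched by gene number to the RefSeq annotation of the assembly Zm-B73-REFERENCE-NAM-5.0, which was used only for names. Of the listed probes, 1823, 886 and 1160 carried a gene and 17377, 13194 and 14840 carried none. A single gene present in RefSeq was found for 1488, 849 and 1100 probes. Probes annotated to several genes (23 on slides 1 to 6 and 1 on slides 13 to 18) were left without a name. RR5, MNB1a, FAD8 and PLTP are named by the array annotation alone. AGP2 (LOC542737) and Agp2 (LOC542072) are different genes.

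The tests, alternatives, gene lists and rule for naming genes were fixed before the data were examined, except where a choice is said to have followed the data. The 19 lists were epidermis and cuticle, knox and corpus, leaf primordium, vascular, histones and DNA replication, cell cycle and mitosis, cytosolic ribosomal proteins, translation factors, photosynthesis, auxin, cytokinin and gibberellin, small RNA and silencing, chromatin, retrotransposons and transposons, mitochondrial energy, cell wall, heat shock and chaperones, defence and stress, and proteasome and ubiquitin. They were matched by gene symbol and by words of a gene description. The annotation gives symbols and no descriptions, so lists defined by descriptions alone matched no probe. Lists of at least 5 probes were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. Adjusted list p-values are over the lists tested on 1 design. The genes named for each design were, among called probes with the same sign on all 6 slides and 1 gene name, the 8 largest differences in each direction. To these were added every called member of the epidermis and knox lists and, from every other list, the 2 smallest p-values. Any further gene named was chosen after its values were seen, and was not put through the alternatives below.

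Alternatives were each reading alone, all readings with the slide as a random block, no dye term, median centring of slides, quantile normalisation between slides, robust eBayes, array weights, leaving out each slide, and, for the lists, an estimated correlation and 1 mean per gene. Chosen after seeing the data were the L2 number of the labels as a random block and a fit without slides 1 and 5. So were fits without another pair of slides of 1 dye orientation. For the agreement between designs, pairs of slides with the same or with other L1 extract numbers were also chosen then. Agreement between designs was measured across genes by Pearson's r and Spearman's rho of the mean difference over a gene's probes, with 100000 permutations.

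The fit was also tested on simulated data with 200 changed probes per design. At a change of 0.5 log units it recovered 89, 66 and 91 of 100 probes (slides 1 to 6, 7 to 12 and 13 to 18), and at 1 log unit 100, 95 and 98 of 100. It called 14, 12 and 10 probes that had not been changed. With lists of 8 probes shifted by 0.3 log units, camera at the preset correlation passed 20 of 20 on every design. Of 20 lists that were not shifted it passed 1, 0 and 0, both counted at an unadjusted p under 0.05. Simulated probes varied independently, so the simulation does not test the preset correlation where probes of a list vary together. The simulated slides also varied independently, with normal noise. Its counts of recovered and false calls therefore do not allow for variation that real slides have in common. The estimated correlations of the real lists ranged from -0.164 (photosynthesis, slides 1 to 6) to 0.536 (cell cycle, slides 13 to 18).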

Results

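Each slide set the L1 against the L2 of the maize shoot apical meristem, and the comparison addresses which genes are expressed unequally in the outer layer and the corpus. The 18 slides were 6 of each of 3 array designs, with L1 in Cy3 on 3 slides of a design and in Cy5 on the other 3. Values were present for 14401 of 19200 probes on slides 1 to 6, 8991 of 14080 on slides 7 to 12 and 14270 of 16000 on slides 13 to 18. The 3 readings of a slide correlated with r between 0.783 and 0.894 on slides 1 to 6, between 0.312 and 0.828 on slides 7 to 12, where slide 11 was lowest, and between 0.424 and 0.660 on slides 13 to 18. Differences below are L1 minus L2 in log units with the limma standard error (n = 6 slides), and 1 log unit is 2-fold at base 2 or 2.72-fold with the natural logarithm. Which layer a sign stands for is likely rather than stated, and was read from the epidermis and knox lists themselves.

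On slides 1 to 6, the outer cell layer genes ocl1, on both probes, and ocl4, on 1 of 2 probes, were higher in L1, ocl2 was not called (0.00, adjusted p = 0.997), and the meristem gene kn1 was higher in L2. The largest named difference was that of ocl4, a homeodomain factor of the outer cell layer family, at 2.12 ± 0.081 (adjusted p = 6.22e-07, higher in 6 of 6 slides). This is 4.34-fold at base 2 or 8.32-fold with the natural logarithm. The other ocl4 probe was at 0.18 ± 0.072 and was not called (adjusted p = 0.272). Its relative ocl1 was higher in L1 at 1.00 ± 0.074 and 0.90 ± 0.077 (adjusted p = 4.38e-05 and 0.000136, 6 of 6 slides), on a pair of probes of the same sequence. kn1, the knotted1 homeobox gene expressed in the meristem, was lower in L1 on all 3 of its probes, at -1.26 ± 0.093, -0.72 ± 0.078 and -0.37 ± 0.071 (adjusted p = 4.37e-05, 0.000599 and 0.0224, lower in 6 of 6 slides).

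Other genes named on slides 1 to 6 lay on both sides. Higher in L1 on 6 of 6 slides were SPP2, a sucrose-phosphate phosphatase, at 1.22 ± 0.145 (adjusted p = 0.00108), and the silicon channel Lsi6 at 1.02 ± 0.186 (adjusted p = 0.0164). MFS18, also higher on 6 of 6 slides, was at 0.91 ± 0.070 (adjusted p = 6.21e-05). The other MFS18 probe was at -0.24 and was not called. EF1-A, translation elongation factor 1-alpha, was higher in L1 on 3 of 24 probes, by 1.67 ± 0.105, 1.43 ± 0.219 and 0.85 ± 0.094 (adjusted p = 1.66e-05, 0.00589 and 0.000703, 6 of 6 slides). The mean over the 24 probes was 0.14. Lower in L1 on 6 of 6 slides were the aldehyde dehydrogenases rf2 (-1.42 ± 0.101, adjusted p = 3.36e-05) and rf2c (-1.24 ± 0.125, adjusted p = 0.000411) and the cystatin cc7 (-1.28 ± 0.146, adjusted p = 0.000903). So were the response regulator RR6, a member of the family that relays cytokinin signals, at -1.27 ± 0.107 (adjusted p = 0.00012) and PIP1-1, a plasma membrane aquaporin, at -1.08 ± 0.169 (adjusted p = 0.00692). The rf2 value is that of 1 called probe of 3, and the mean over the 3 was -0.61. AGP2 was called on 6 of its 9 probes, the strongest at -1.23 ± 0.075 and -1.15 ± 0.081 (adjusted p = 1.3e-05 and 3.22e-05), with a mean over the 9 of -0.64. Not called on slides 13 to 18 were SPP2 (0.51), Lsi6 (0.08), cc7 (-0.18) and rf2c (-0.64 and -0.04), and Lsi6 was at 1.04 and not called on slides 7 to 12; these differences between designs were not tested.

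Over all probes of slides 1 to 6, limma called 409 of 14401, with 216 higher in L1 and 193 higher in L2, and 67 of them differed by more than 1 log unit. Unadjusted p-values under 0.05 numbered 2133, where 720 are expected by chance, and 62 called probes had a gene name. The dye term was called on 415 probes, some of which may also be among the 409. On slides 7 to 12 and 13 to 18 it was called on 1 and 0 probes. The count depended on single slides, since it was 241 without slide 1, 211 without slide 2, 217 without slide 3 and 242 without slide 5, and it was 78 without slides 1 and 5, whose L1 and L2 extract numbers differ. That fit kept 4 slides, only 1 of them with L1 in Cy3, fewer than the 2 per orientation otherwise required. Every fit with a slide left out also has fewer degrees of freedom, which alone can lower its count. Leaving out slides 1 and 3 or slides 3 and 5, the other pairs of that orientation, gave 85 and 77 calls, so the low count was not particular to slides 1 and 5. Without slides 1 and 5 the calls of SPP2 (adjusted p = 0.0802, range over its alternatives 0.000366 to 0.0802), rf2c (0.0710, range 0.000108 to 0.0710) and the middle kn1 probe (0.0769, range 9.47e-07 to 0.0769) ended. Lsi6 was also lost without slide 1, 2 or 5 (adjusted p up to 0.0796; 0.572 without slides 1 and 5; range 0.00506 to 0.572). The weakest kn1 probe was lost without any one of slides 1 to 5 (up to 0.118; 0.406 without slides 1 and 5; range 1.5e-05 to 0.406).

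**Figure D1:**
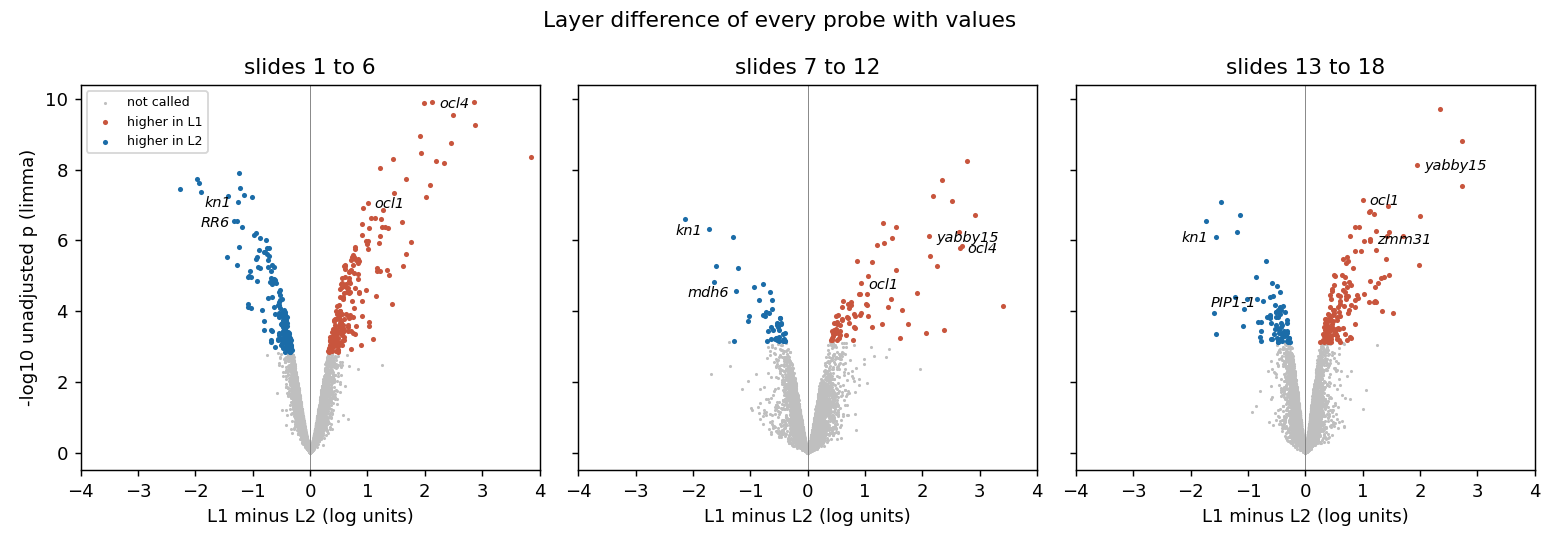
Layer difference in log units against the unadjusted limma p of every probe with values, 1 panel per array design. Coloured points are the 409, 129 and 224 called probes, with ocl1 on the L1 side and kn1 on the L2 side of every panel.

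On slides 7 to 12, ocl4, ocl1 and 1 of 2 probes of ocl3 were higher in L1, joined by a yabby gene and by knox8. ocl4 was higher in L1 by 2.65 ± 0.181 (adjusted p = 0.000846), 6.28-fold at base 2 or 14.2-fold with the natural logarithm. yabby15, of the yabby family of leaf and lateral organ factors, was higher by 2.12 ± 0.130 (adjusted p = 0.000602). ocl1 was higher by 0.93 ± 0.090 (adjusted p = 0.00535) and ocl3 by 0.80 ± 0.120 (adjusted p = 0.0295), while the other ocl3 probe was at -0.15 and was not called. The proline-rich protein gene prp2 was higher on both probes, by 1.02 ± 0.121 and 0.67 ± 0.109 (adjusted p = 0.0138 and 0.0400), and the glutamine synthetase gln5 by 0.83 ± 0.111 on 1 of 3 probes (adjusted p = 0.0202). All of these were higher in 6 of 6 slides.

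In the other direction on slides 7 to 12, kn1 was at -1.72 ± 0.099 (adjusted p = 0.000483, lower in 6 of 6 slides), and its other probe at -0.27 ± 0.100 was not called (adjusted p = 0.304). Both probes of the malate dehydrogenase mdh6 were lower in L1, at -1.24 ± 0.130 and -1.03 ± 0.137 (adjusted p = 0.00811 and 0.0202, 6 of 6 slides). The pathogenesis-related gene pr5 (-0.58 ± 0.098, adjusted p = 0.0471), the Dof-type factor MNB1a (-0.54 ± 0.091, adjusted p = 0.0462) and rf2 (-0.43 ± 0.075, adjusted p = 0.0484) were lower as well, each in 6 of 6 slides. limma called 129 of 8991 probes, 80 higher in L1 and 49 higher in L2, with 44 beyond 1 log unit and 16 with a gene name. Unadjusted p-values under 0.05 numbered 1245, where 450 are expected by chance. Leaving out slide 7, 8, 9, 10, 11 or 12 gave 52, 65, 51, 38, 58 or 48 calls. Without each of the 6 slides in turn, knox8, pr5 and rf2 were lost (adjusted p up to 0.154, 0.137 and 0.197), ocl3 without any but slide 8 (up to 0.145) and MNB1a without any but slide 7 (up to 0.163). The prp2 probes were lost without slide 7, 8, 10 or 12 (up to 0.0900) and 7, 9, 10, 11 or 12 (up to 0.169). gln5 was lost without slide 8, 9, 10 or 11 (up to 0.0874), and the weaker mdh6 probe without slide 7, 9, 10 or 12 (up to 0.109).

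On slides 13 to 18, yabby15 was again among the largest differences and the MADS-box gene zmm31 came beside it. yabby15 was higher in L1 by 1.94 ± 0.064 and 1.31 ± 0.123 (adjusted p = 3.52e-05 and 0.00363). zmm31 was higher by 1.13 ± 0.073 (adjusted p = 0.000557). zmm31 was not called on the other designs, where its probe on slides 7 to 12 was at 0.34 and its 4 probes on slides 1 to 6 lay between -0.34 and -0.03. The difference between designs was not tested. ocl1 was higher by 1.00 ± 0.045 (adjusted p = 0.000196), ocl3 by 0.46 ± 0.049 (adjusted p = 0.00674) and fps1, a farnesyl diphosphate synthase, by 0.75 ± 0.060 (adjusted p = 0.00166). EF1-A was higher on 4 of 14 probes, by 1.34 ± 0.174, 0.86 ± 0.128, 0.77 ± 0.098 and 0.60 ± 0.108 (adjusted p = 0.0147, 0.0244, 0.0140 and 0.0484). All of these were higher in 6 of 6 slides. The mean over the 14 EF1-A probes was 0.23. On slides 7 to 12, 0 of 8 EF1-A probes were called, with a mean of 0.086.

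Lower in L1 on slides 13 to 18, in 6 of 6 slides, was kn1 at -1.56 ± 0.100 (adjusted p = 0.000514), although its other 2 probes were at -0.26 and 0.02 and were not called. PIP1-1 was lower on 4 of 5 probes, at -1.08 ± 0.163, -0.74 ± 0.087, -0.59 ± 0.102 and -0.55 ± 0.090 (adjusted p = 0.0270, 0.00965, 0.0433 and 0.0362). AGP2 (-0.83 ± 0.120, adjusted p = 0.0219, 1 of 2 probes), LOC606477 (-0.77 ± 0.112, adjusted p = 0.0224) and the response regulator RR5 (-0.51 ± 0.076, adjusted p = 0.0259) were also lower. limma called 224 of 14270 probes, 145 higher in L1 and 79 higher in L2, with 43 beyond 1 log unit and 34 with a gene name. Unadjusted p-values under 0.05 numbered 1834, where 714 are expected by chance. Leaving out slide 13, 14, 15, 16 or 17 gave 92, 92, 88, 108 or 121 calls. Calls ended without slide 13, 14, 15 or 16 for AGP2 (adjusted p up to 0.101), without slide 13, 14, 16 or 17 for LOC606477 (up to 0.0984) and without any but slide 15 for RR5 (up to 0.103). PIP1-1 was lost on 3 probes without any but slide 18 (up to 0.0897, 0.162 and 0.147) and on the fourth without slide 15 (0.0523). Over all alternatives the adjusted p of these probes reached 0.0897, 0.285, 0.192 and 0.332. The 3 strongest EF1-A probes were lost without slides of the set 13, 14, 15, 17 and 18 (up to 0.0675, 0.112 and 0.0579). The calls of yabby15, zmm31, ocl1, ocl3, fps1 and kn1 held without any one slide. That of ocl3 ended in 2 of its 15 alternatives (adjusted p up to 0.196).

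**Figure D2:**
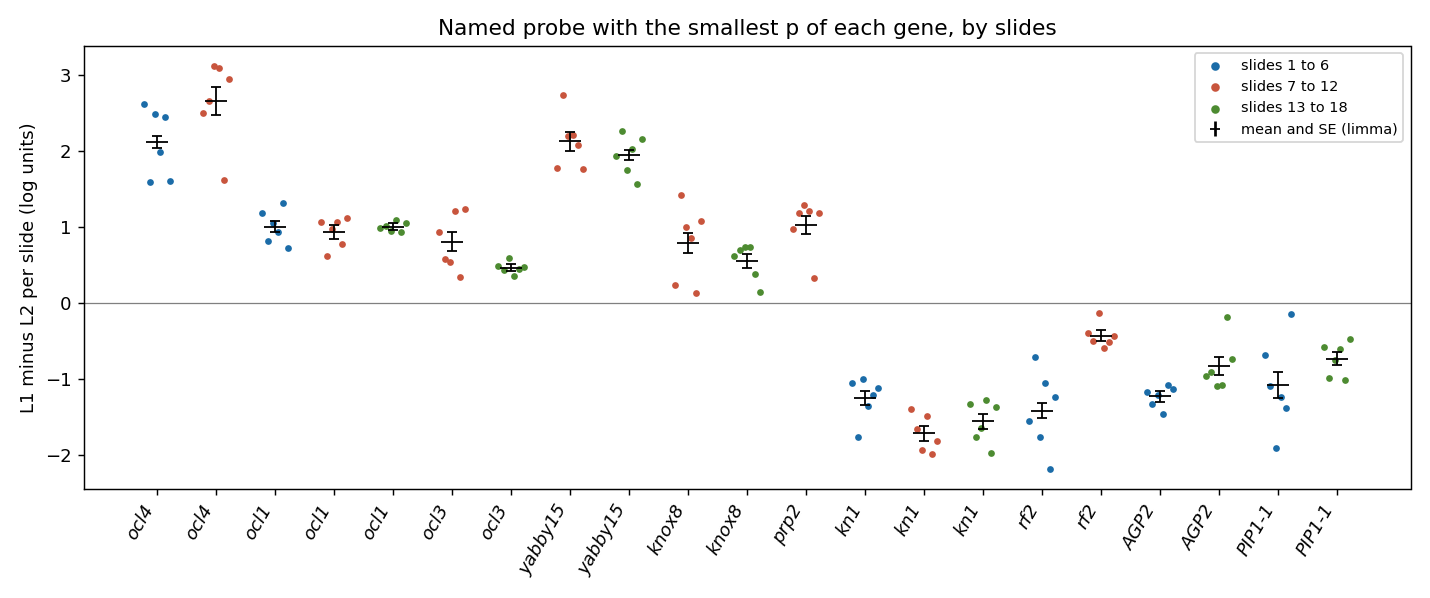
Difference on each slide in log units for the named probe with the smallest p of each gene, coloured by array design, with the limma mean and standard error in black. ocl4, ocl1, ocl3, yabby15, knox8 and prp2 lie above 0 on every slide shown, and kn1, rf2, AGP2 and PIP1-1 lie below 0.

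The list of epidermis and cuticle genes was shifted to L1 on slides 1 to 6, and on slides 7 to 12 by camera at the preset correlation only. On slides 1 to 6, 3 of its 6 probes were higher in L1 over all probes and 5 adjusted over the list alone, with a median of 0.71. For this list camera gave an adjusted p of 5.51e-09 (adjusted p = 0.0256 with an estimated correlation, range over the alternatives 8.27e-10 to 0.0256). On slides 7 to 12, 3 of 6 were higher by either count, with a median of 0.47 and an adjusted p of 0.00249 (adjusted p = 0.305 with an estimated correlation, which ended the call; range 0.000322 to 0.305). On slides 13 to 18, 2 of 4 were higher, and 3 adjusted over the list alone, too few probes for the list test. The wax gene gl8 was at 0.52 ± 0.165 on slides 1 to 6 and 0.35 ± 0.078 on slides 13 to 18 (adjusted p = 0.159 and 0.0987, higher in 4 and 6 of 6 slides). The receptor kinase gene cr4 was at 0.14 and -0.11 on slides 7 to 12 and 13 to 18, and ocl2 at 0.00 on slides 1 to 6, none of them called. Because the sign of all values was read from this list and the knox list, neither is independent evidence of direction.

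Within the knox and corpus list, kn1 was called higher in L2 on at least 1 probe of each design, and knox8, measured on slides 7 to 12 and 13 to 18 only, was higher in L1. knox8, another knotted-like homeobox gene, was higher in L1 on slides 7 to 12 at 0.78 ± 0.135 (adjusted p = 0.0483). Its probes on slides 13 to 18 were at 0.55 ± 0.092 and 0.59 ± 0.104 (adjusted p = 0.0398 and 0.0451), and all 3 were higher in 6 of 6 slides. Its other probe on slides 7 to 12 was at 0.58 ± 0.125 and was not called (adjusted p = 0.0943). The knox8 calls were lost without any one of slides 7 to 12 (adjusted p up to 0.154) and, on both probes, without any one of slides 13 to 17 (up to 0.176 and 0.193). The related genes knox7, knox3 and lg3 were not called on any design, with differences between -0.14 (lg3) and 0.29 (knox7). Of the 6 list probes on slides 1 to 6, 3 were lower in L1, by either count, all of them kn1, with a median of -0.19. The list's adjusted p was 0.00521 there (adjusted p = 0.120 with an estimated correlation and 0.319 with 1 mean per gene, range 0.00132 to 0.319). The counts on slides 7 to 12 were 1 higher and 1 lower of 7 (2 and 1 adjusted over the list alone; adjusted p = 0.656, and 0.769 with an estimated correlation). For slides 13 to 18 they were 2 higher and 1 lower of 12 by either count. There the median was 0.02 and the mean -0.03, and the test's direction was L1 (adjusted p = 0.984, and 0.988 with an estimated correlation).

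In the leaf primordium list, yabby genes lay on the L1 side, whereas rs2, and the rld1 probes of slides 1 to 6 and 7 to 12, lay on the L2 side and were not called. On slides 1 to 6, lg2, a bZIP factor of the ligule, was at 0.46 ± 0.079 (adjusted p = 0.0122), yab14 at 0.66 ± 0.119 (adjusted p = 0.0158) and yab10 at 0.49 ± 0.113 (adjusted p = 0.0490). These were 3 of 15 probes, each higher in 6 of 6 slides, and 5 were higher adjusted over the list alone. On slides 7 to 12, yabby15 and yab9 (0.46 ± 0.066, adjusted p = 0.0264) were higher, 2 of 8 probes and 5 adjusted over the list alone. On slides 13 to 18, both yabby15 probes and 1 of 2 probes of ns1, a homeobox gene of the leaf margin (0.54 ± 0.088, adjusted p = 0.0363), were higher. These were 3 of 18, with 7 higher and 1 lower adjusted over the list alone. rs2, the MYB gene expressed in leaf primordia, was at -0.36 ± 0.133, -0.20 ± 0.119 and -0.32 ± 0.088 on the 3 designs and was not called on any. The list passed camera on slides 7 to 12 (median 0.40, adjusted p = 7.88e-05) and 13 to 18 (median 0.17, adjusted p = 0.00275), and did not on slides 1 to 6 (median 0.09, adjusted p = 0.0691). With an estimated correlation both calls ended (adjusted p = 0.305 and 0.277; ranges over the alternatives 8.25e-06 to 0.305 and 0.000529 to 0.277; adjusted p = 0.505 on slides 1 to 6). The list passed on slides 1 to 6 in 6 of 12 alternatives, among them without slide 3 (adjusted p = 0.0481) and without slide 6 (0.0221), with a range of 0.00635 to 0.505. lg2 was lost without slide 2 or 5 (up to 0.0556) and yab14 without slide 2, 3 or 5 (up to 0.0802). Both were lost without slides 1 and 5 together (0.435 and 0.132; ranges 0.0041 to 0.435 and 6.74e-05 to 0.132). yab9 was lost without any one of slides 7 to 12 (up to 0.130).

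Heat shock genes, which tissue handling can also raise, were higher in L1 on slides 1 to 6 on 2 of 25 probes, by either count. Both were probes of the small heat shock gene hsp18a, at 0.67 ± 0.095 (adjusted p = 0.00327, 6 of 6 slides) and 0.71 ± 0.136 (adjusted p = 0.0206, 5 of 6 slides). The third hsp18a probe was at 0.07 ± 0.079 and was not called (adjusted p = 0.755). The call at 0.71 was lost without slide 3 or 5 (up to 0.0955), and both calls without slides 1 and 5 together (0.164 and 0.147; ranges 8.81e-07 to 0.164 and 0.000645 to 0.147). The list's median was 0.07, and its adjusted p was 0.0206 (adjusted p = 0.232 with an estimated correlation; 0.0508 without slide 4 and 0.0953 without slide 5; range 0.00891 to 0.319). On slides 13 to 18, limma called 0 of 13 heat shock probes (2 at an unadjusted p under 0.05; 1 adjusted over the list alone; list adjusted p = 0.183, and 0.891 with an estimated correlation). That list passed there without slide 14 (adjusted p = 0.0206) and with the M reading (0.0159; range 0.0159 to 0.891). The 4 hsp18a probes were at 0.41 ± 0.083 (adjusted p = 0.0734), 0.38, -0.03 and -0.12. It called 0 of 3 on slides 7 to 12, all of them hsp101, and 0 had an unadjusted p under 0.05.

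Genes of the cytokinin and gibberellin list were measured on few probes, and the list did not hold RR6, hk3 and an1, of the same pathways and called lower in L1 on slides 1 to 6 (-1.27, -0.43 and -0.67). RR5 was lower in L1 on slides 13 to 18, 1 of 7 probes called and 2 adjusted over the list alone, both of them RR5. The list's median there was 0.00 and its mean -0.12, and the test, with direction L2, gave an adjusted p of 0.269 (adjusted p = 0.631 with an estimated correlation). For slides 1 to 6, limma called 0 of 4 probes (2 at an unadjusted p under 0.05). Adjusted over the list alone, 2 were lower, RR4 at -0.33 ± 0.080 (adjusted p = 0.0666, lower in 6 of 6 slides) and RR5 at -0.32 ± 0.092 (adjusted p = 0.120, 5 of 6 slides). The list held only these 2 genes there, and its other 2 probes lay on the L1 side. On slides 7 to 12 limma called 0 of 3, and 0 had an unadjusted p under 0.05.

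No probe of the cell cycle and replication lists was called. limma called 0 of 36, 8 and 13 cell cycle and mitosis probes on slides 1 to 6, 7 to 12 and 13 to 18, and 0 of 9, 6 and 5 probes of histones and DNA replication. None of these probes had an unadjusted p under 0.05. The cell cycle probes stood for only 9, 6 and 6 genes, and the histone and replication probes for 4, 4 and 3. On slides 1 to 6 the cell cycle genes included the tubulins tua3, tua4, TUA1, TUBB2 and tub6. Both lists therefore cover few genes of cell division. The list tests gave adjusted p-values of 0.865, 0.105 and 0.984 for cell cycle and 0.865, 0.368 and 0.984 for histones, and the gene farthest from 0, cdc2 on slides 7 to 12, was at -0.28 ± 0.133 (adjusted p = 0.401). There 7 of 8 cell cycle probes and 6 of 6 histone and replication probes lay on the L2 side, and the cell cycle list had an unadjusted p of 0.0472. It passed toward L2 with the L reading (adjusted p = 0.0462) and without slide 7 (0.0340), but not with an estimated correlation (0.408; range 0.0340 to 0.408). Probes of the vascular, photosynthesis, auxin, small RNA and defence lists were also not called. The vascular list held only 2, 2 and 3 genes on the 3 designs, on slides 1 to 6 sh1 and ss2 alone. It therefore says little of vascular tissue as a whole. Vascular genes gave 0 of 14, 5 and 9 (0 at an unadjusted p under 0.05; list adjusted p = 0.865, 0.446 and 0.984). Photosynthesis genes gave 0 of 5, 9 and 4 (0, 2 and 0 at an unadjusted p under 0.05, the 2 being probes of pdk1 at 0.39 and 0.30; list adjusted p = 0.865 and 0.105, with too few probes on slides 13 to 18). On slides 7 to 12 the photosynthesis list passed toward L1 without slide 11 (adjusted p = 0.0399, range over the alternatives 0.0399 to 0.511). Auxin genes gave 0 of 3, 1 and 1, and small RNA and silencing genes 0 of 4 and 2 on slides 1 to 6 and 13 to 18. The small RNA and silencing probes were all of 1 gene, lbl1. Defence and stress gave 0 of 1 on slides 1 to 6. In these lists limma gave 0 probes at an unadjusted p under 0.05, and the probes were too few for a list test. Ribosomal proteins, translation factors, chromatin, transposons, mitochondrial energy, cell wall and proteasome, 7 lists in all, matched 0 probes on every design.

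**Figure D3:**
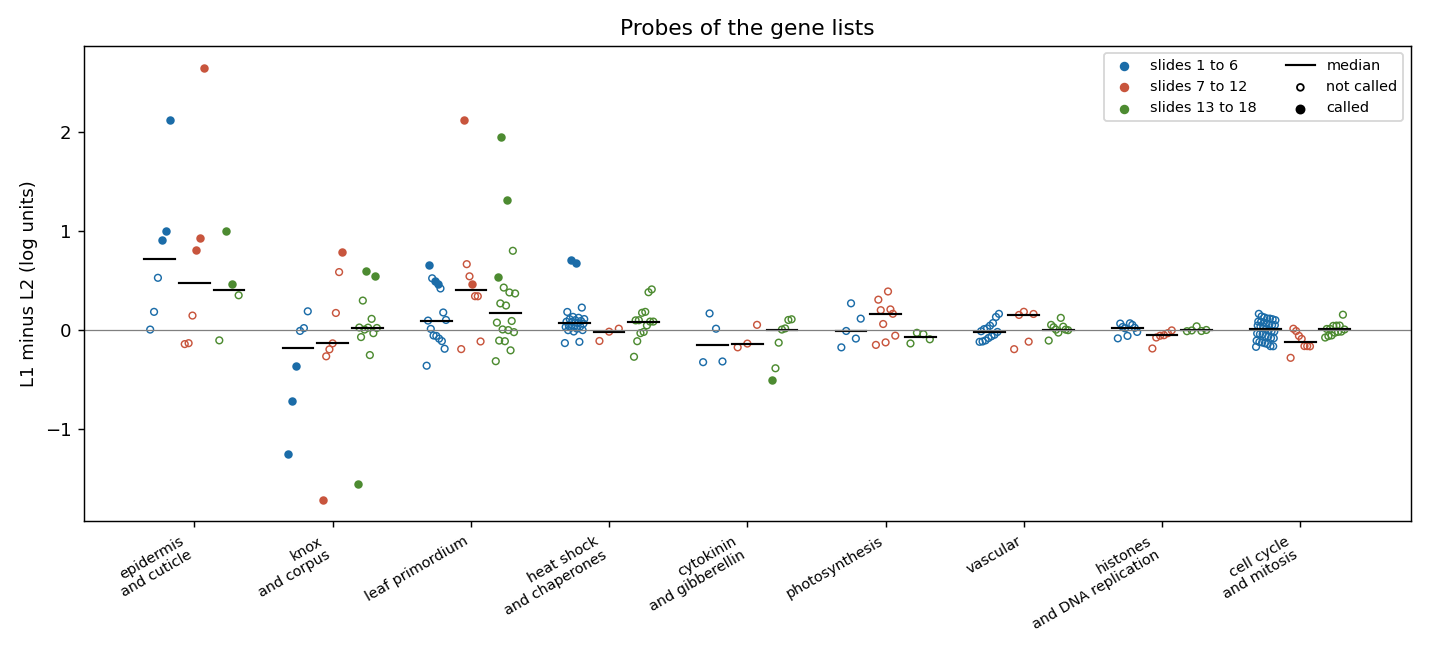
Difference in log units of every probe of 9 gene lists, coloured by array design, with filled points for called probes and a bar at the median. The epidermis medians are 0.71, 0.47 and 0.40, and the called kn1 and knox8 probes of the knox list lie on opposite sides of 0.

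Layer differences of genes measured on more than 1 array design correlated between the designs. Of 824 named genes, 512 were measured on 2 or 3 designs, and 65 were called on any, 39 higher in L1 and 26 higher in L2. Of these, 10 were higher in L1 on at least 2 designs (TE1, ocl1, ocl3, ocl4, yabby15, knox8, prp2, EF1-A, ccr2 and pdi2). Higher in L2 were 6 (kn1, PIP1-1, AGP2, Agp2, LOC606477 and rf2), and 0 were called in opposite directions. A gene counted on a design where 1 or more of its probes was called, which favours genes with many probes. EF1-A had 24, 8 and 14 probes on the 3 designs, with 3, 0 and 4 called. Across genes, the mean differences correlated with Pearson's r of 0.715 and Spearman's rho of 0.498 between slides 1 to 6 and 7 to 12 (261 genes, 70.5% of the same sign). Between slides 1 to 6 and 13 to 18, r was 0.647 and rho 0.587 (382 genes, 69.9%), and between slides 7 to 12 and 13 to 18, r was 0.718 and rho 0.575 (301 genes, 69.1%). The permutation p, two-sided, was 1e-05 for each, the smallest that 100000 permutations can give, and 1e-05 after Benjamini-Hochberg adjustment over this family of 3. These correlations are across genes, which are not independent replicates, and the designs share RNA extracts and 21, 158 and 74 annotated sequences. The permutation of genes does not account for shared extracts. Because the reading of slides 1 to 6 and the direction of slides 13 to 18 were taken from likeness to the other designs, the positive sign and the absence of opposite calls were partly fixed beforehand.

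A comparison chosen after seeing the data used 2 slides per design, 1 of each dye orientation, with L1 extract numbers 1 and 2 or 3 and 4. With L1 numbers 1 and 2 on one design against 3 and 4 on the other, r was 0.484 to 0.612 and rho 0.278 to 0.410 over 6 comparisons, with 55.5% to 66.8% of genes of the same sign. With the same L1 numbers on both designs, r was 0.519 to 0.626 and rho 0.369 to 0.484 over 6 comparisons, with 60.5% to 68.1% of the same sign. By the labels, slide 1 carries L2 number 2, and slides 7 and 13 carry L2 number 1. The comparisons of slides 1 and 2 at the same L1 numbers therefore did not share every L2 extract. The permutation p was 1e-05 for r and for rho in each of the 12, also after adjustment over this family. With the single slide of each design whose extract the other lacks, r was 0.228, 0.290 and 0.200, rho was 0.0768, 0.229 and 0.121, and 49.4%, 58.4% and 51.5% of genes had the same sign. The first and last of these shares were near the even split that chance gives, and the single slides were not balanced for the dye.

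**Figure D4:**
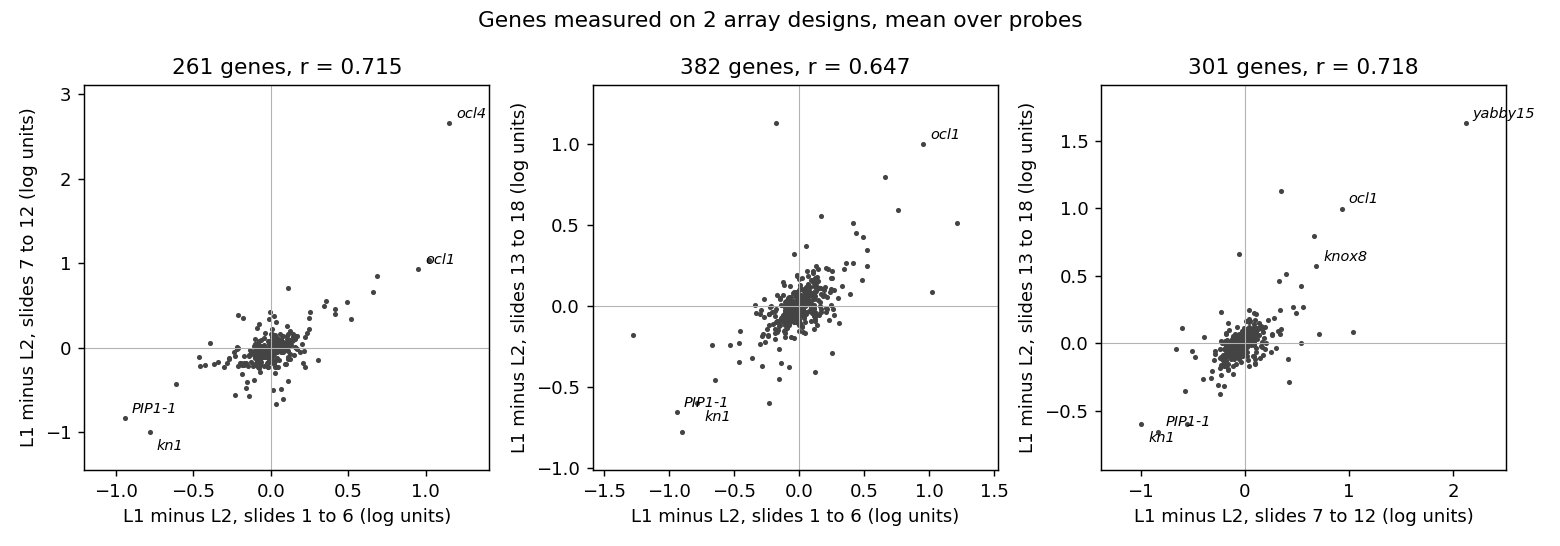
Mean difference in log units of each gene on one array design against another, 1 point per gene. ocl1 lies in the upper right and kn1 and PIP1-1 in the lower left of each panel.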

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

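The tests on knox8 and on rs2, and the stricter readings of the slide 1 test and of the test of a shared L2 extract, were chosen only after the results were seen.

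Single slides stood far from the other 5 in 4 of 116 groups of 6 values, where a rate of 1 in 20 would give about 5.8. That rate is for independent normal values. The probe values here kept their dye term, which can hide a single slide, and many probes were picked for small p-values. These counts therefore do not show whether single slides stood out more often than by chance. For the weakest kn1 probe of slides 1 to 6, slide 6 was at -0.147 and the others lay between -0.473 and -0.355. For the stronger prp2 probe of slides 7 to 12, slide 11 was at 0.323 and the others between 0.968 and 1.28. For the RR5 probe of slides 13 to 18 that was not called, slide 17 was at 0.0732 and the others between -0.627 and -0.392. The standard deviation over probes was 0.327 on slide 18 and between 0.270 and 0.279 on slides 13 to 17.

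The layer calls were set against other splits of the slides. A design of 6 slides allows 10 splits into 3 and 3, too few for a share under 0.05, and only 1 of the 10, the real one, gave as many calls on each design. The real split called 409 probes on slides 1 to 6, 129 on slides 7 to 12 and 224 on slides 13 to 18, and the highest other split called 0, 0 and 1. Each other split mixes the dye orientations, so a layer difference enters its error and lowers its calls. Such counts therefore do not measure the rate of false calls. The other splits had 192 to 1452, 119 to 645 and 209 to 2386 probes at an unadjusted p under 0.05, so that on slides 13 to 18 another split exceeded the 1834 of the real one. On every design the highest of these unadjusted counts belonged to the slides with L1 extract numbers 1, 2 and 4 (slides 1, 2 and 4, slides 7, 8 and 10, and slides 13, 14 and 16) against the rest.

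kn1 was higher in L2 and knox8 higher in L1, although both are knotted-like homeobox genes of the interior list. An unrelated transcript on 1 knox8 probe was considered as the cause. Each of the 4 probes lay above 0 by at least 4.67 standard errors, in 6 of 6 slides. None was more than 1.16 standard errors from their mean of 0.626, so the L1 side did not rest on 1 probe. Because knox8 was picked after its probes had been called, this outcome was largely fixed beforehand. It cannot exclude an unrelated transcript read by a sequence present on both designs. Reading of kn1 transcript was argued against as the cause of the L1 side, since it would pull to L2 and the lowest knox8 probe was at 0.547 ± 0.092, though a smaller share of kn1 in their signal stays open. The 4 probes hold only 2 sequences, each on both designs, so a wrong annotation common to them remains open and was not tested. That knox8 is unequally expressed in the layers stays a hypothesis, and its calls were lost without most single slides.

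Some leaf primordium genes, yabby15 by the largest difference, were called higher in L1, on 3 of 15, 2 of 8 and 3 of 18 probes of their list. One explanation is that L1 captures held more primordium cells; then rs2, expressed through the primordium, would lie on the L1 side too. rs2 lay on the L2 side by more than 2 standard errors on 2 of the 3 designs (-0.36 ± 0.133, -0.20 ± 0.119 and -0.32 ± 0.088). This explanation cannot be told apart from others by that test, which rests on 1 gene picked after its values were seen and not called (adjusted p = 0.228, 0.517 and 0.178), on designs that share extracts. Primordium surface cells without their interior, and an L1 expression of yabby genes within the meristem, stay open and were not tested.

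The labels give slides 1 and 2, and slides 5 and 6, the same L2 extract number. Whether these slides shared an L2 extract cannot be told apart: the residuals of slides 5 and 6 correlated at -0.232 and those of slides 1 and 2 at -0.0342, where a value at or below 0 had been set beforehand as speaking against it. That bound was too weak, since the other 7 pairs ran from -0.331 to 0.323 and both values lie within that spread. Whether slide 1 instead held L2 extract 1 cannot be told apart either: its residuals correlated with those of slides 7 and 13 (extract 1) at a mean of 0.188, near the 0.167 of slides 2 to 4 with their own numbers and above the -0.101 with the slides of extract 2. This met what had been expected, before the value was seen, of a slide with extract 1, but slides 1, 7 and 13 share L1 extract 1 in either case, which keeps this open.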

How the results depend on the processing

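The L2-name block, the fits without 2 slides and the comparison of designs with 2 slides each were chosen only after the results were seen. Of the called named probes, 13 of 22 on slides 1 to 6, 5 of 15 on slides 7 to 12 and 6 of 19 on slides 13 to 18 kept their call in every setting, and 0 changed direction. Signal over background was not given in the sources used here, and what limits the number of calls was not tested. Requiring a value in every column removed no probe and was therefore not run. For the changes below the cause was not tested.

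On slides 1 to 6 the count of 409 became 261 with the L reading, 258 with no dye term, 669 with array weights and 993 with all readings and the slide as a block. It was 577 in the L2-name block, whose correlation was -0.207, and 78 without slides 1 and 5. Without the other pairs of slides of 1 dye orientation it was 85 (slides 1 and 3), 77 (3 and 5), 203 (2 and 4), 229 (2 and 6) and 176 (4 and 6). On slides 7 to 12 the count of 129 became 82 with the L reading, 76 with the H reading and 649 with the slide as a block. On slides 13 to 18 the count of 224 became 79 with the L reading, 625 with array weights and 984 with the slide as a block. The fits with the slide as a block counted every reading toward their degrees of freedom, so their counts do not rest on 1 replicate per slide. A shared L2 extract would give a positive correlation in the L2-name block, so its 577 calls do not allow for sharing. Leaving out 1 slide gave 211 (without slide 2) to 417 (without slide 6), 38 (without slide 10) to 65 (without slide 8) and 88 (without slide 15) to 231 (without slide 18) calls. With Cy5 taken as the numerator, the share of calls higher in L1 was 52.8%, 62.0% and 64.7%, and it was 46.3%, 47.0% and 52.7% with the slide as a block. With Cy3 as the numerator these would be the shares higher in L2.

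The called named probes numbered 13 of 22 without slides 1 and 5, 8 and 9 of 15 with the L and H readings of slides 7 to 12, and 7 of 19 with the L reading of slides 13 to 18. Without 1 slide they were 17 to 22, 5 to 8 and 8 to 17. Lists passing camera fell from 3 to 1 on slides 1 to 6, from 2 to 0 on slides 7 to 12 and from 1 to 0 on slides 13 to 18 with an estimated correlation, where 2, 0 and 1 had an unadjusted p under 0.05. They were 2 with the M reading of slides 13 to 18, 2 to 4 and 2 to 3 without 1 slide on the first designs and 1 to 2 on slides 13 to 18. The fry p-values under 0.05, not adjusted over the lists, were 1.46e-05 (epidermis), 0.000337 (knox) and 0.0255 (heat shock) on slides 1 to 6. On slides 7 to 12 they were 0.00177 (epidermis), 0.0404 (knox) and 0.00427 (leaf primordium). On slides 13 to 18 they were 0.000582 (leaf primordium) and 0.0145 (cytokinin and gibberellin). Pearson's r between the designs, 0.715, 0.647 and 0.718, was 0.228, 0.290 and 0.200 with 1 slide of each design. Those slides differ from the full set in number, in extract and in dye balance at once. With 2 slides per design balanced for the dye, r was 0.484 to 0.612 with different L1 extract numbers and 0.519 to 0.626 with the same L1 numbers.

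Only probes that were not called changed sign. Without slides 1 and 5, pcna1 was at -0.0147 and lbl1 at -0.0033. hsp101 on slides 7 to 12 was at 0.0450 with the L reading, 0.0063 with the H reading, 0.0263 with array weights and -0.109 to 0.0703 without 1 slide. On slides 13 to 18, MCM6 was at 0.0291 with the L reading, 0.0229 with array weights and -0.0445 to 0.0368 without 1 slide. There rca1 was at 0.0122 with the L reading, arf1 at -0.0640 with the L reading, -0.0328 with array weights and -0.0480 to 0.0757 without 1 slide, and lbl1 at -0.117 to 0.0294 without 1 slide.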

Other observations

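All genes in this part were chosen after their values were seen, and none was put through the alternatives of the processing. TE1, the terminal ear1 gene for an RNA-binding protein that acts in leaf initiation, was higher in L1 on all 3 array designs, by 0.41 ± 0.073, 0.40 ± 0.069 and 0.51 ± 0.047 (adjusted p = 0.0135, 0.0483 and 0.00363, higher in 6 of 6 slides of each). ccr2 was higher in L1 by 0.76 ± 0.092 on slides 1 to 6 and 0.59 ± 0.092 on slides 13 to 18 (adjusted p = 0.00124 and 0.0298, 6 of 6 slides). The protein disulfide isomerase gene pdi2 was higher on 1 of 2 probes of each of these designs, by 0.60 ± 0.069 and 0.70 ± 0.075 (adjusted p = 0.000889 and 0.00693, 6 of 6 slides). On slides 1 to 6, 4 of 7 probes of lim1, of the LIM-domain family, were higher in L1, by 0.33 to 0.59, and so was prp2 by 0.68 ± 0.088 (adjusted p = 0.00182), each in 6 of 6 slides. FAD8, a fatty acid desaturase, was higher in L1 on slides 13 to 18 by 0.66 ± 0.070 (adjusted p = 0.00652, 6 of 6 slides) but was at -0.06 and not called on slides 7 to 12.

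On the L2 side of slides 1 to 6 lay an1, an early enzyme gene of gibberellin synthesis, at -0.67 ± 0.076 (adjusted p = 0.000897, lower in 6 of 6 slides), and at -0.24 and not called on slides 13 to 18. The histidine kinase gene hk3 was at -0.43 ± 0.083 (adjusted p = 0.0225, 6 of 6 slides), and at -0.20 and not called on slides 7 to 12. tip1, an aquaporin of the vacuolar membrane, was lower on 3 of 7 probes, at -0.55 ± 0.094, -0.54 ± 0.088 and -0.47 ± 0.076 (adjusted p = 0.0111, 0.00933 and 0.00865, 6 of 6 slides). Agp2 was at -0.53 ± 0.076 there and at -0.43 ± 0.070 on 1 of 2 probes of slides 13 to 18 (adjusted p = 0.00366 and 0.0349, 6 of 6 slides). LOC606477 was at -0.90 ± 0.105 on slides 1 to 6 (adjusted p = 0.000948, 6 of 6 slides). The catalase gene cat2 was at -0.43 ± 0.075 on slides 13 to 18 (adjusted p = 0.0451, 6 of 6 slides).

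Slides of like dye orientation that carry the same L1 extract number on different designs correlated beyond the layer difference. After the fitted layer and dye terms were removed, 13 of 13 such pairs of like dye orientation correlated above 0 across shared genes, with a median r of 0.165 and a highest r of 0.328. The 41 pairs of different numbers and like orientation had a median of -0.0506 and ranged from -0.360 to 0.431. The highest of these, slides 6 and 18, exceeded every pair of the same number. The 2 pairs of the same number and opposite orientation were at 0.0183 and 0.0690. Both values lie within the range of the 52 pairs of different numbers and opposite orientation, -0.203 to 0.261. Most of the 13 pairs also shared their L2 number. What is left of the 3 slides of an orientation sums to 0 in each design, so the pairs are not independent. Slide 18 had a mean r of 0.000305 with the other slides of its dye orientation.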
